A study of Streptomyces coelicolor with 4 samples.

How the data were processed

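RNA was measured in 4 cultures of Streptomyces coelicolor M145, 2 with DMSO and 2 with ARC2, grouped by the sample titles. Per the labels' protocols, total RNA was extracted with phenol and chloroform by a modified Kirby procedure, and the labels call the cultures biological replicates. Per the submitters' processing notes, Trimmomatic 0.32.3, Bowtie2 2.2.6.2, HTSeq 0.6 and DESeq2 2.11.38 were used; their parameters, the genome build and the strand setting are not given in the sources used here. The authors deposited whole-number counts per gene for each library, not normalised. The authors also deposited a table of 1 comparison, whose values and column order are those of DESeq2 output. It holds a signal per gene (the mean of normalised counts), log2 fold changes with standard errors, a score (the Wald statistic), and p-values with adjusted p-values, all by the authors. Its adjusted p-values equal a Benjamini-Hochberg adjustment over all 7853 genes. Since it carries no header, its sign was set by its correlation with the count files.

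Without a stated strand setting, reads of overlapping or antisense genes cannot be told apart, and reads shared by near-identical genes could be split or lost in counting. Ribosomal RNA rows held 0.217% to 0.315% of counts and 3 SCOs rows 6.20% to 6.93%. The rows of plasmids SCP1 and SCP2, which M145 lacks, held 1 count in DMSO replicate 2 and 0 in the others. Rows outside genes were not used here, since the count files hold gene rows alone.

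The files give locus tags and do not pair them with names. The supplied gene table was of the M1152 assembly, and 0 of its 7842 rows matched a locus tag, so it gave no names. The names, functions and members of the 42 gene lists come from general knowledge of the locus tags of this organism and were not checked against an annotation. The lists, the tests and the rule for named genes were fixed before the data were examined. The 20 lists given with named members were chosen after the list results were seen, and the result of each of the 42 lists is printed. Another 11 lists defined by product keywords could not be run without product names. Checks of GC content and gene length were void, because no annotation in use here gave a value for these genes.

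Counts were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr with a minimum count of 10 and a minimum total of 15, TMM scaling, and the quasi-likelihood F test with treatment as the only term and the newer, bias-adjusted fit. Benjamini-Hochberg adjustment covered all 7730 tested genes, and an adjusted p below 0.05 was a call. All tests were two-sided. Standard errors were the log2 fold change over the root of the F statistic, and 95% intervals used the total degrees of freedom. Gene lists with at least 3 tested genes were tested with camera in limma 3.58.1, with a preset correlation of 0.01 and again with an estimated correlation. Of 42 lists camera called 9 higher and 8 lower with the preset correlation and 0 with an estimated one, where 4 lists had an unadjusted p below 0.05. The fry test of whether a list's genes move one way called 0 lists, with 12 at an unadjusted p below 0.05, and its mixed test, for change in either direction, called 19. Neither fry test compares a list with other genes.

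Named genes were afsR, afsS and the cluster-situated regulators, the 8 largest rises and 8 largest falls among called genes with a mean of at least 10 CPM and groups that did not overlap, up to 4 members per described list by smallest p, and fabI. Of the 8 largest falls, the 2 with the lowest values are named with SCO4568 and sodF, and the remaining ones are nuo genes or lie outside the lists.

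With 10591836 to 14111685 counts per library and 2 cultures per group, the biological coefficient of variation was 0.154. In simulated counts with known changes, made from the means and library sizes of these libraries, 68.7% of 99 genes changed by 1 log2 unit and 86.9% of 99 changed by 2 were recovered among 7693 genes tested, with 1 false call in 155. Smaller changes can be missed. The simulation drew each gene independently, with no deviation shared by same-numbered libraries, so its rates may not hold for the real counts. Replicates of a group differed by more than sampling noise, with a chi-square per degree of freedom of 28.5 for DMSO and 14.8 for ARC2, so all 4 libraries were kept apart. Alternatives were DESeq2 size factors, library size only, other count filters, DESeq2 1.42.0, limma-voom, the older edgeR fit, tests with a fold threshold, a replicate block, leaving out non-coding rows, and leaving out each library. In the last, the lone library of a group is assumed to vary like the other group.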

Results

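Gene expression was measured by RNA sequencing in Streptomyces coelicolor M145, a soil bacterium that makes several pigmented antibiotics. Starter cultures were grown for 8 h, given either ARC2, a small molecule described by the submitters as a chemical elicitor, or its solvent DMSO, and grown for a further 10 h. The labels describe 2 biological replicate cultures per treatment, 4 libraries in all. The libraries held 10591836 counts for DMSO replicate 1, 14111685 for DMSO replicate 2, 11001252 for ARC2 replicate 1 and 11871626 for ARC2 replicate 2. Of 8299 rows, 7853 had a count in at least 1 library and 7730 were tested. The design addresses 1 question: which genes differ in expression between cultures with ARC2 and cultures with DMSO, in a series whose title ties the response to the regulators afsR and afsS.

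With ARC2, all 22 genes of the actinorhodin cluster, all 22 of the undecylprodigiosin cluster and 31 of 40 of the calcium-dependent antibiotic cluster rose, while 1 gene of the last fell. All 7 genes of the carotenoid cluster, all 5 of the SapB cluster, 9 of 10 for chaplins and rodlins, and all 14 of respiratory complex I fell. As lists, each was called by camera with its preset correlation and none with an estimated one (adjusted p = 0.452 to adjusted p = 0.946 with an estimated correlation). Both regulators named in the title rose modestly. Normalised expression (CPM, each count scaled to library size with TMM) of afsR (SCO4426), a pleiotropic regulator of antibiotic production, was 239 ± 4.98 CPM with DMSO and 377 ± 36.6 with ARC2 (SD, n = 2), a log2 fold change of 0.66 (SE 0.142, edgeR adjusted p = 0.00709). Its neighbour afsS (SCO4425) had a log2 fold change of 0.67 (SE 0.172, edgeR adjusted p = 0.0192). In all, 619 genes were called higher and 709 lower at an edgeR adjusted p below 0.05, and 227 and 218 of these differed at least 2-fold. Both ARC2 libraries lay on the same side of both DMSO libraries for 53.1% of tested genes. The share would be 33.3% if all orders of the 4 libraries were equally likely. Same-numbered libraries deviated together (correlation 0.66) and genes vary together, so the comparison gives no test.

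The cluster-situated regulators of antibiotic production did not all move alike. The activator of the actinorhodin cluster, actII-ORF4 (SCO5085), rose 4.80-fold, from 19.6 ± 0.345 to 94.4 ± 21.1 CPM (SD, n = 2; log2 fold change 2.26, SE 0.174, edgeR adjusted p = 5.17e-06). The undecylprodigiosin activator redD (SCO5877) rose by 1.60 on the log2 scale (SE 0.260, edgeR adjusted p = 0.00130), and scbA (SCO6266), the gene of gamma-butyrolactone synthesis, rose by 3.02 (SE 0.197, edgeR adjusted p = 1.39e-06). Smaller rises were found for redZ (SCO5881; log2 fold change 0.54, edgeR adjusted p = 0.0299) and for cdaR (SCO3217; 0.96, edgeR adjusted p = 0.0265). The redZ call was lost without DMSO replicate 1 (0.34, adjusted p = 0.127) and without ARC2 replicate 2 (0.43, adjusted p = 0.142), and that of cdaR without DMSO replicate 1 (0.75, adjusted p = 0.155) and with no filter on low counts (0.96, adjusted p = 0.0511). The coelimycin activator cpkO (SCO6280) and the receptor gene scbR (SCO6265) did not pass the test, with log2 fold changes of 0.35 (edgeR adjusted p = 0.427) and -0.12 (edgeR adjusted p = 0.677). Also in the coelimycin cluster, cpkN (SCO6288) was called higher (1.04, edgeR adjusted p = 0.0130) and scbR2 (SCO6286) was not called (0.21, edgeR adjusted p = 0.565). Both were named after their values were seen. The cpkO value was 0.15 without DMSO replicate 1, 0.54 without DMSO replicate 2, 0.62 without ARC2 replicate 1 and 0.031 without ARC2 replicate 2, and passed the test in none of these. Over the whole list of 37 tested regulators, 12 were called higher and 3 lower, or 13 and 7 adjusted over the list alone. Among the 3 that fell was wblA (SCO3579), a regulator of the WhiB family, with a log2 fold change of -0.99 (SE 0.165, edgeR adjusted p = 0.00148). The list's median was 0.20 (camera adjusted p = 0.0158; adjusted p = 0.946 with an estimated correlation), and the call was lost without DMSO replicate 1 (0.021, adjusted p = 0.128) and without ARC2 replicate 2 (0.109, adjusted p = 0.117).

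**Figure D1:**
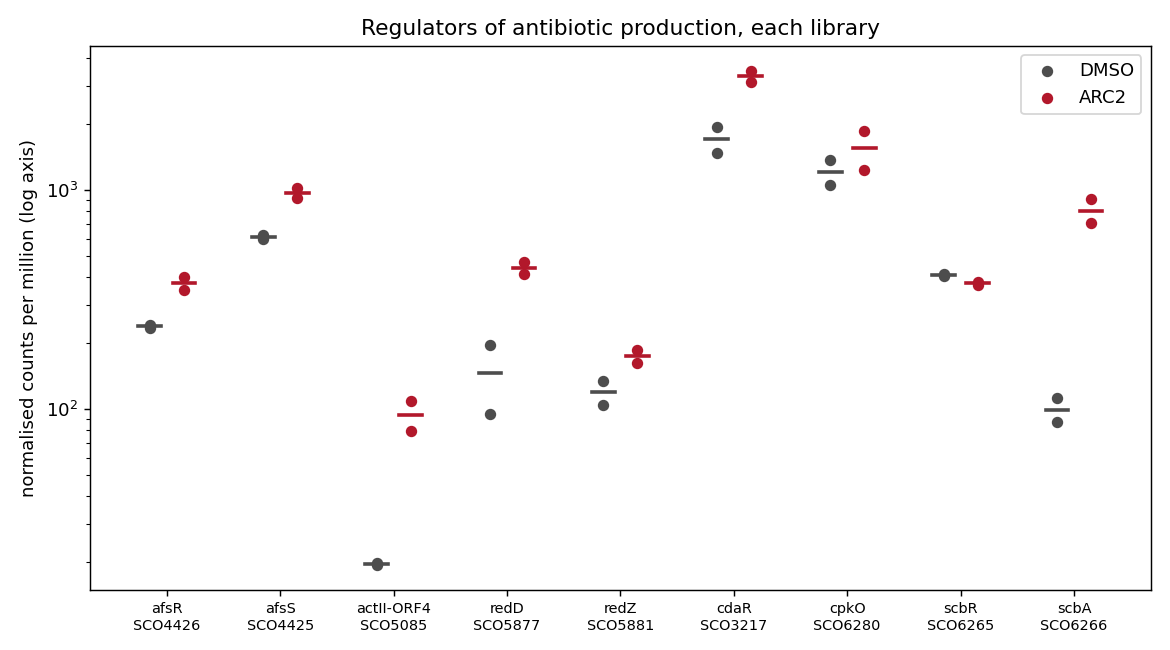
Normalised CPM on a log axis for the 9 regulators named by rule, with each point 1 library and each bar the mean of 2 libraries. The ARC2 libraries lie above the DMSO libraries for afsR, afsS, actII-ORF4, redD, redZ, cdaR and scbA, and the groups overlap for cpkO.

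All 22 genes of the actinorhodin cluster, which encodes a blue polyketide, were called higher, and 22 adjusted over the list alone. Their median log2 fold change was 3.63 (camera adjusted p = 1.68e-113; adjusted p = 0.452 with an estimated correlation). The 8 genes that rose most by the rule for named genes all belonged to this cluster, with SCO5071 first at 4.75 (SE 0.249, edgeR adjusted p = 4.85e-07). The level of SCO5074 went from 10.3 ± 0.935 to 217 ± 35.8 CPM (SD, n = 2), a log2 fold change of 4.39 (SE 0.181, edgeR adjusted p = 3.27e-07). The cluster took 0.0384% and 0.0347% of all counts in the DMSO libraries and 0.235% and 0.292% in the ARC2 libraries.

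All 22 genes of the cluster for undecylprodigiosin, a red tripyrrole, were called higher as well, and 22 adjusted over the list alone. The median log2 fold change was 2.29 (camera adjusted p = 6.53e-27; adjusted p = 0.557 with an estimated correlation). SCO5887 had a log2 fold change of 2.41 (SE 0.229, edgeR adjusted p = 2.91e-05) and SCO5884 one of 2.39 (SE 0.259, edgeR adjusted p = 7.91e-05). The DMSO libraries differed from each other by a median of 1.27 on the log2 scale over these genes, and the 4 pairings of an ARC2 with a DMSO library gave medians from 1.70 to 3.18.

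Of 40 tested genes of the calcium-dependent antibiotic, a lipopeptide, 31 were called higher and 1 lower, or 34 and 2 adjusted over the list alone. The median log2 fold change was 1.13 (camera adjusted p = 5.29e-14; adjusted p = 0.946 with an estimated correlation). SCO3249 rose by 1.47 (SE 0.194, edgeR adjusted p = 3.20e-04) and SCO3215 by 1.30 (SE 0.213, edgeR adjusted p = 0.00139). The member called lower was SCO3219, at -1.13 (SE 0.222, edgeR adjusted p = 0.00429). In all, 34 members had positive and 6 negative values. Negative values without a call included SCO3216 (-0.67, edgeR adjusted p = 0.289), absA1 (SCO3225; -0.39, edgeR adjusted p = 0.283) and absA2 (SCO3226; -0.45, edgeR adjusted p = 0.115). These genes and SCO3219 were named after their values were seen. The cluster held 5.03% and 6.59% of counts in the DMSO libraries and 9.12% and 9.48% in the ARC2 libraries.

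The coelimycin cluster, a type I polyketide cluster, gave a result that depended on which library was left out. Of its 20 tested genes, 6 were called higher and 0 lower, or 8 and 0 adjusted over the list alone, with a median log2 fold change of 0.56 (camera adjusted p = 0.00232; adjusted p = 0.946 with an estimated correlation). SCO6270 had a log2 fold change of 1.68 (SE 0.299, edgeR adjusted p = 0.00238). With the replicate block the list's median was 0.64 (camera adjusted p = 3.61e-07). The list's call was lost without DMSO replicate 1 (median 0.0657, adjusted p = 0.161) and without ARC2 replicate 2 (0.153, adjusted p = 0.158), and the median was 1.13 without DMSO replicate 2 and 0.857 without ARC2 replicate 1. Without ARC2 replicate 2 the calls of SCO6269 (1.77, adjusted p = 0.0600), SCO6271 (1.12, adjusted p = 0.108) and SCO6272 (0.99, adjusted p = 0.0935) were also lost. Without DMSO replicate 1 the log2 fold changes of SCO6271 and SCO6272 were 1.01 and 0.84, and without DMSO replicate 2 that of SCO6271 was 2.35. With DESeq2 the calls of SCO6270 (1.72, adjusted p = 0.0524), SCO6271 (1.58, adjusted p = 0.136) and SCO6272 (1.33, adjusted p = 0.12) were lost.

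**Figure D2:**
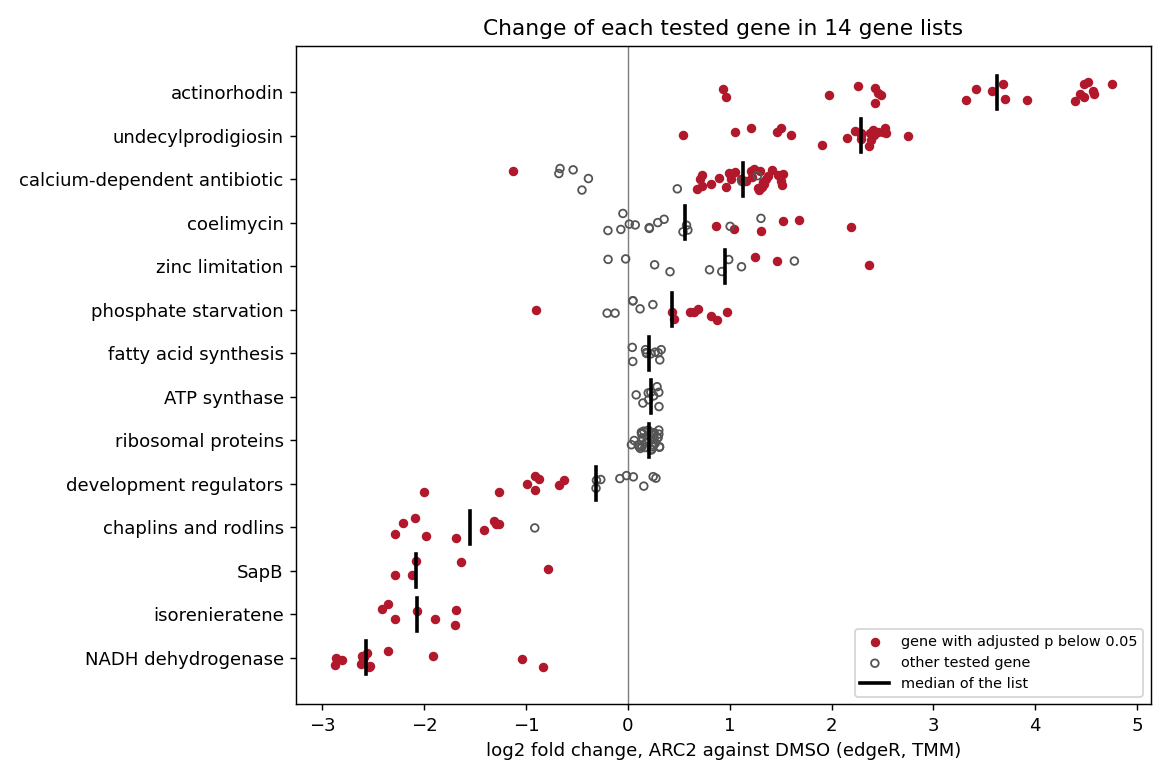
Log2 fold change with ARC2 against DMSO for each tested gene of 14 gene lists, with filled points for genes at an edgeR adjusted p below 0.05, open points for other genes and a bar at each list's median. Medians run from 3.63 for the actinorhodin cluster to -2.58 for the NADH dehydrogenase genes.

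Genes of aerial growth and of a carotenoid moved the other way. All 7 genes of the isorenieratene cluster, which makes a carotenoid, were called lower (7 adjusted over the list alone), with a median log2 fold change of -2.08 (camera adjusted p = 4.66e-29; adjusted p = 0.452 with an estimated correlation). All 5 genes of the SapB cluster were called lower (5 adjusted over the list alone), with a median of -2.08 (camera adjusted p = 2.14e-15; adjusted p = 0.452 with an estimated correlation). Among them, ramC (SCO6681) went from 420 ± 9.40 to 99.4 ± 1.55 CPM (SD, n = 2), and ramS (SCO6682), the gene of the SapB precursor, had a log2 fold change of -2.29 (SE 0.187, edgeR adjusted p = 8.62e-06). Of 10 genes for chaplins and rodlins, hydrophobic proteins of the aerial surface, 9 were called lower and 10 adjusted over the list alone. Their median was -1.55 (camera adjusted p = 1.36e-13; adjusted p = 0.557 with an estimated correlation), and chpH (SCO1675) had a log2 fold change of -2.09 (SE 0.181, edgeR adjusted p = 1.42e-05).

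Among 17 tested regulators of development, 8 were called lower and 0 higher, and 8 and 0 adjusted over the list alone. The median was -0.31 (camera adjusted p = 2.35e-04; adjusted p = 0.557 with an estimated correlation). The sporulation gene whiH (SCO5819) fell most among those named, from 250 ± 17.6 to 62.2 ± 4.36 CPM (SD, n = 2), 4.01-fold lower (edgeR adjusted p = 1.98e-06). The genes ssgA (SCO3926) and whiI (SCO6029) had log2 fold changes of -1.27 (SE 0.140, edgeR adjusted p = 8.55e-05) and -0.91 (SE 0.167, edgeR adjusted p = 0.00283).

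All 14 nuo genes, which encode the NADH dehydrogenase of the respiratory chain, were called lower (14 adjusted over the list alone). Their median log2 fold change was -2.58 (camera adjusted p = 2.87e-62; adjusted p = 0.452 with an estimated correlation), and the 4 library pairings gave medians from -2.73 to -2.44. SCO4568 went from 834 ± 110 to 115 ± 3.89 CPM (SD, n = 2; edgeR adjusted p = 8.37e-07). Of 9 ATP synthase genes 0 were called, with a median of 0.22 (camera adjusted p = 0.270), and of 31 ribosomal protein genes 0 were called, with a median of 0.21 (camera adjusted p = 0.0616). The ribosomal protein list was called without ARC2 replicate 1 (0.28, adjusted p = 0.0165) and with library size as the only scaling (0.17, adjusted p = 0.0273). Without ARC2 replicate 2 the ribosomal protein median was 0.11 (adjusted p = 0.312) and the ATP synthase median 0.13 (adjusted p = 0.496). In both lists 0 genes had an unadjusted edgeR p below 0.05, and DESeq2 and limma-voom called 0.

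Of 12 genes of the tricarboxylic acid cycle, 5 were called higher and 1 lower, or 6 and 1 adjusted over the list alone (median 0.41, camera adjusted p = 0.0479; adjusted p = 0.946 with an estimated correlation). SCO4809 rose by 0.79 (SE 0.160, edgeR adjusted p = 0.00488) and fumB (SCO5042) fell by 0.81 (SE 0.137, edgeR adjusted p = 0.00175). The list's call was lost with DESeq2 size factors (0.43, adjusted p = 0.0782) and without DMSO replicate 1 (0.32, adjusted p = 0.149), DMSO replicate 2 (0.47, adjusted p = 0.0604) or ARC2 replicate 2 (0.37, adjusted p = 0.119). Of 13 glycolysis genes 0 were called, although all 13 had negative values and 5 had an unadjusted edgeR p below 0.05 (median -0.19, camera adjusted p = 0.244). DESeq2 and limma-voom called 0 of them, and the median was -0.12 without ARC2 replicate 1. Of 10 fatty acid synthesis genes 0 were called, with log2 fold changes from 0.04 to 0.33 and a median of 0.20 (camera adjusted p = 0.235), 0 had an unadjusted edgeR p below 0.05, and DESeq2 and limma-voom called 0. The enoyl reductase gene fabI (SCO1814) had a log2 fold change of 0.18 (95% interval -0.10 to 0.46, edgeR adjusted p = 0.431), with 0.060 without DMSO replicate 1 and 0.28 without DMSO replicate 2. The list's median was 0.10 and 0.38 without these libraries, and the list was called in neither case. The gene fabD (SCO2387) had 0.33 (edgeR adjusted p = 0.183) and was called without DMSO replicate 2 (0.51, adjusted p = 0.0131), with 0.13 without DMSO replicate 1.

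Of 12 genes linked to zinc limitation, 3 were called higher and 0 lower, and 3 and 0 adjusted over the list alone (median 0.96, camera adjusted p = 4.12e-04; adjusted p = 0.452 with an estimated correlation). These were SCO2505, SCO2506 and SCO2507, with log2 fold changes of 2.37 (SE 0.143, edgeR adjusted p = 8.37e-07), 1.46 and 1.24. The list's median was 0.53 without DMSO replicate 2 and 0.036 without ARC2 replicate 1. Of 15 phosphate starvation genes, 8 were called higher and 1 lower, and 8 and 1 adjusted over the list alone (median 0.44, camera adjusted p = 0.0247; adjusted p = 0.946 with an estimated correlation). The phosphate-binding protein gene pstS (SCO4142) rose by 0.97 (SE 0.142, edgeR adjusted p = 6.35e-04) and glpQ2 (SCO1968) fell by 0.91 (SE 0.136, edgeR adjusted p = 7.69e-04). The phosphate call was lost with library size as the only scaling (0.40, adjusted p = 0.0933), without DMSO replicate 1 (0.35, adjusted p = 0.0872) and without ARC2 replicate 1 (0.43, adjusted p = 0.108).

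Of 4 ectoine genes, for a compatible solute, 3 were called higher and 0 lower, or 4 and 0 adjusted over the list alone (median 0.76, camera adjusted p = 0.0134; adjusted p = 0.946 with an estimated correlation), and ectC (SCO1866) had 0.93 (SE 0.171, edgeR adjusted p = 0.00291). The ectoine call was lost without DMSO replicate 1 (0.52, adjusted p = 0.0872) and without ARC2 replicate 1 (0.60, adjusted p = 0.0587). The gene ectA (SCO1864; 0.69, edgeR adjusted p = 0.0179) lost its call without ARC2 replicate 1 (0.53, adjusted p = 0.116) and had 0.44 without DMSO replicate 1.

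Of 6 genes linked to thiol oxidative stress, 5 were called lower and 0 higher, or 6 and 0 adjusted over the list alone (median -0.58, camera adjusted p = 0.00917; adjusted p = 0.946 with an estimated correlation), and the list was not called without DMSO replicate 1 (-0.43, adjusted p = 0.0511). The thioredoxin gene trxA (SCO3889) had -1.02 (SE 0.164, edgeR adjusted p = 0.00121). The call of mca (SCO4967; -0.56, edgeR adjusted p = 0.0168) was lost without ARC2 replicate 1 (-0.51, adjusted p = 0.0612). Those of mshA (SCO4204; -0.72, edgeR adjusted p = 0.0237) and trxB (SCO3890; -0.61, edgeR adjusted p = 0.0275) were lost without DMSO replicate 1 (-0.41, adjusted p = 0.117 and -0.40, adjusted p = 0.0645), ARC2 replicate 1 (-0.74, adjusted p = 0.0789 and -0.55, adjusted p = 0.0945) and ARC2 replicate 2 (-0.72, adjusted p = 0.110 and -0.66, adjusted p = 0.0621). The mshA call was also lost with library size only (-0.76, adjusted p = 0.0545) and a minimum of 10 CPM (-0.70, adjusted p = 0.0513).

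Of 11 genes for peroxide and superoxide defence, 1 was called higher and 4 lower, or 2 and 4 adjusted over the list alone (median -0.20, camera adjusted p = 0.0264; adjusted p = 0.557 with an estimated correlation). The list's median was 0.012 without ARC2 replicate 2 (adjusted p = 0.117), -0.067 without DMSO replicate 1 and -0.35 without ARC2 replicate 1. Within it the superoxide dismutase gene sodF (SCO2633) fell by 2.78 (SE 0.197, edgeR adjusted p = 2.74e-06) and sodF2 (SCO0999) by 1.52 (SE 0.145, edgeR adjusted p = 2.99e-05). Of 13 heat shock genes, 2 were called lower and 0 higher, and 2 and 0 adjusted over the list alone, with a median of -0.26 (camera adjusted p = 0.691). The heat shock median was -0.39 without DMSO replicate 1, -0.11 without ARC2 replicate 1 and -0.42 without ARC2 replicate 2. The genes called were clpP2 (SCO2618; -0.64, edgeR adjusted p = 0.0226) and clpP1 (SCO2619; -0.53, edgeR adjusted p = 0.0364), whose calls were lost without ARC2 replicate 1 (-0.55, adjusted p = 0.0696 and -0.49, adjusted p = 0.0799) and with DESeq2 size factors (-0.61, adjusted p = 0.0523 and -0.51, adjusted p = 0.0970). Of 11 cell envelope stress genes, 2 were called higher and 0 lower, and 2 and 0 adjusted over the list alone, with a median of 0.14 (camera adjusted p = 0.379). That median was 0.31 without DMSO replicate 1, 0.042 without ARC2 replicate 1 and 0.30 without ARC2 replicate 2. The genes called were vanS (SCO3589; 0.65, edgeR adjusted p = 0.00744) and vanR (SCO3590; 0.70, edgeR adjusted p = 0.00990), a vancomycin resistance sensor and regulator, and both calls were lost without ARC2 replicate 2 (0.61, adjusted p = 0.0517 and 0.57, adjusted p = 0.0869).

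Of 17 gas vesicle genes, 4 were called lower and 0 higher, or 7 and 0 adjusted over the list alone, with a median of -0.46 (camera adjusted p = 0.114); the list was called without ARC2 replicate 1 (-0.54, adjusted p = 0.0437). SCO6503 had -0.79 (SE 0.163, edgeR adjusted p = 0.00574) and -0.53 without DMSO replicate 2. The calls of the other 3, SCO6504 (-0.53, edgeR adjusted p = 0.0474), SCO6505 (-0.97, edgeR adjusted p = 0.00709) and SCO6506 (-0.59, edgeR adjusted p = 0.0284), depended on the libraries and settings. Without DMSO replicate 2 they had -0.26 (adjusted p = 0.396), -0.75 (adjusted p = 0.101) and -0.37 (adjusted p = 0.254). Without ARC2 replicate 2 they had -0.54 (adjusted p = 0.141), -0.90 (adjusted p = 0.0599) and -0.53 (adjusted p = 0.146), and without ARC2 replicate 1 SCO6504 and SCO6506 had -0.51 (adjusted p = 0.147) and -0.66 (adjusted p = 0.0607). The SCO6504 call was also lost with DESeq2 size factors (adjusted p = 0.0607), no filter on low counts (adjusted p = 0.0608), a minimum of 10 CPM (adjusted p = 0.0557) and DESeq2 (adjusted p = 0.117), and that of SCO6506 with DESeq2 (adjusted p = 0.0987).

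The deoxysugar cluster had 4 of 21 genes called lower and 0 higher, or 5 and 0 adjusted over the list alone (median -0.33, camera adjusted p = 0.0102; adjusted p = 0.946 with an estimated correlation). This call was lost without ARC2 replicate 1 (-0.058, adjusted p = 0.514), and the median was -0.66 without ARC2 replicate 2. The remaining lists were not called by camera. Coelichelin had 2 of 11 genes called lower (2 adjusted over the list alone; median -0.33, camera adjusted p = 0.204), and the hopanoid cluster 1 higher and 1 lower of 13 (1 and 4 adjusted over the list alone; -0.19, camera adjusted p = 0.519). Nitrogen assimilation had 1 higher and 1 lower of 15 (1 and 1 adjusted over the list alone; 0.21, camera adjusted p = 0.510), with gdhA (SCO4683) at 0.81 and glnR (SCO4159) at -0.45. DNA repair had 1 lower of 9, lexA (SCO5803) at -0.81 (1 adjusted over the list alone; -0.024, camera adjusted p = 0.665). The nitrate reductases had 1 lower of 12 (1 adjusted over the list alone; -0.41, camera adjusted p = 0.204) and lantibiotic cluster 2 had 1 higher of 6 (1 adjusted over the list alone; -0.10, camera adjusted p = 0.875). Without ARC2 replicate 1 the medians were -0.21 for coelichelin, -0.066 for the hopanoid cluster, 0.045 for nitrogen assimilation, 0.017 for DNA repair, -0.75 for the nitrate reductases and -0.47 for lantibiotic cluster 2. The coelichelin median was -0.20 and that of DNA repair -0.15 without DMSO replicate 1, and the hopanoid median was -0.12 and that of DNA repair 0.024 without DMSO replicate 2. Without ARC2 replicate 2, DNA repair was at -0.11 and lantibiotic cluster 2 at 0.22. The genes gdhA, glnR and lexA were named after their values were seen.

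In 14 lists with 149 tested genes, 0 genes were called by edgeR; 14 genes had an unadjusted edgeR p below 0.05, DESeq2 called 1 and limma-voom 0. Besides those given, their medians were 0.40 for desferrioxamine (camera adjusted p = 0.665), 0.24 for the grey spore pigment (0.716), 0.63 for coelibactin (0.241), -0.15 for flaviolin (0.795) and -0.24 for the volatile terpenoids (0.568, with 1 gene lower adjusted over the list alone). They were -0.38 for the polyunsaturated fatty acid-type cluster (camera adjusted p = 0.665), 0.041 for lantibiotic cluster 1 (0.995), 0.37 for the orphan peptide synthetase cluster (0.347), 0.023 for cell division and wall genes (0.689) and -0.21 for the osdK/osdR region (0.484). The other 13 of these lists had 0 genes called adjusted over the list alone. Some lists were weakly expressed, so that a change could be missed: the grey spore pigment genes had group means from 1.63 to 8.66 CPM. Coelibactin was called without DMSO replicate 1 (1.22, adjusted p = 0.0171), and its median was 0.080 without DMSO replicate 2, 0.14 without ARC2 replicate 1 and 0.99 without ARC2 replicate 2. The orphan peptide synthetase median was 0.092 without DMSO replicate 2. In addition, without DMSO replicate 2 the nitrate reductases (-0.55, adjusted p = 0.00144) and the osdK/osdR region (-0.87, adjusted p = 8.88e-04) were called. The left chromosome arm had 77 of 1374 genes higher and 102 lower (64 and 96 adjusted over the list alone; median 0.031, camera adjusted p = 0.875), and the right arm 180 of 1912 higher and 144 lower (180 and 143; 0.045, camera adjusted p = 0.377). Several of these medians changed sign without 1 library. Without DMSO replicate 1 the polyunsaturated fatty acid-type cluster was at 0.12, cell division and wall at -0.037 and the osdK/osdR region at 0.38. Without DMSO replicate 2 the grey spore pigment was at -0.25, lantibiotic cluster 1 at -0.16, the left arm at -0.055 and the right arm at -0.029. Without ARC2 replicate 1 desferrioxamine was at -0.32, the grey spore pigment at -0.49, lantibiotic cluster 1 at -0.083, the left arm at -0.074 and the right arm at -0.084, and without ARC2 replicate 2 cell division and wall was at -0.035.

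**Figure D3:**
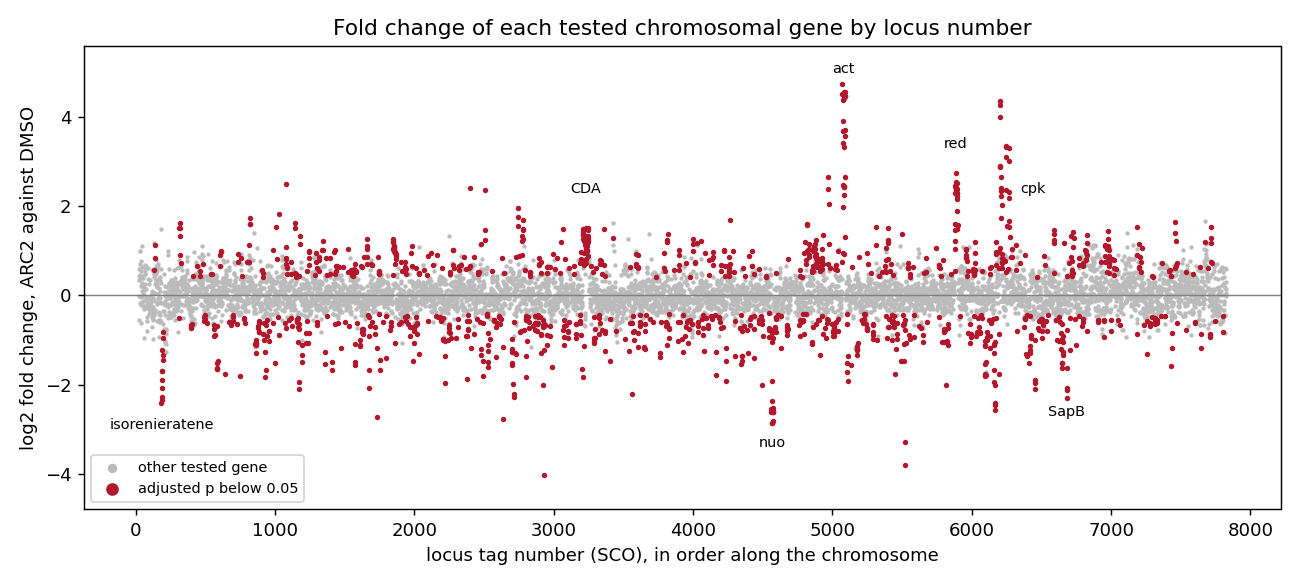
Log2 fold change with ARC2 against DMSO for each tested chromosomal gene, ordered by locus tag number, with red points at an edgeR adjusted p below 0.05. Words mark the actinorhodin (act), undecylprodigiosin (red), calcium-dependent antibiotic (CDA), coelimycin (cpk), NADH dehydrogenase (nuo), isorenieratene and SapB genes; the actinorhodin genes reach 4.75 and the nuo genes -2.88.

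Outside the gene lists, the genes that fell most by the rule for named genes were SCO2927, from 1117 ± 244 to 68.8 ± 2.18 CPM (SD, n = 2; log2 fold change -4.02, SE 0.211, edgeR adjusted p = 4.85e-07), and SCO5521, with -3.82 (SE 0.186, edgeR adjusted p = 3.81e-07). The authors' deposited table, made from the same libraries, called 530 genes higher and 547 lower. Its log2 fold changes correlated with those of edgeR across 7730 genes (Pearson r = 0.989), where genes are not independent replicates. The slope of its values on those of edgeR was 0.88, so its changes were smaller on the whole. Both called 1027 genes, all 1027 with the same sign, the authors' deposited table alone 50 and edgeR alone 301. In the coelimycin cluster the deposited table called SCO6269 (adjusted p = 4.02e-05). It did not call SCO6270 (adjusted p = 0.0692), SCO6271 (adjusted p = 0.178) or SCO6272 (adjusted p = 0.162).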

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

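Leaving out the SCOr, SCOt and SCOs rows together was chosen after seeing the data (625 higher, 725 lower). Counts of genes called stayed within 1.5 times the 619 higher and 709 lower under other scalings, filters and tests and without any single library, with 3 exceptions: the replicate block (932 and 1104), a test against a log2 fold change of 1 (78 and 82), and a required log2 fold change of 1 (227 and 218). The last 2 ask for more by construction. Same-numbered libraries deviated together (correlation 0.66). The replicate number alone was not taken as pairing, so the replicate block is an alternative and not the main fit. All 1328 calls were kept under the block, and coelibactin was then called (median 0.60, camera adjusted p = 0.0447). Similar totals elsewhere did not mean the same genes. Of the 1328 calls, 281 were not made by DESeq2, which gave adjusted p-values for 6031 genes. DESeq2 size factors lost 129 and library size only lost 127. Calls were also lost without each single library. Every call shared with another setting kept its sign. Leaving out 1 library unbalances replicate number against treatment. Values and calls that changed without 1 library can therefore hold a difference shared by same-numbered libraries. Lists called, 17, went to 0 with an estimated correlation and to 0 with fry. There the lists of actinorhodin (median 3.63), undecylprodigiosin (2.29), the calcium-dependent antibiotic (1.13) and coelimycin (0.56) did not pass. In that order, camera with an estimated correlation gave adjusted p 0.452, 0.557, 0.946 and 0.946, and fry gave 0.0747, 0.167, 0.249 and 0.487. For camera only the correlation changed, estimated from 4 libraries at 0.942, 0.957, 0.965 and 0.952 against the preset 0.01. The preset thus treats genes of a cluster as nearly independent. The cause of the loss with fry was not tested. Without 1 library the coelimycin median ran from 0.0657 to 1.13. It was low without DMSO replicate 1 (0.0657) or ARC2 replicate 2 (0.153), and high without ARC2 replicate 1 (0.857) or DMSO replicate 2 (1.13). A higher level in both replicate 2 libraries would give this order. With the replicate block the median was 0.64 and the list stayed called (camera adjusted p = 3.61e-07). The spread alone therefore does not show that the rise is unstable. Why the replicates differed was not tested. Medians that changed sign without 1 library ran from -0.32 to 0.91 for desferrioxamine, -0.49 to 0.71 for the grey spore pigment, -0.83 to 0.12 for the polyunsaturated fatty acid-type cluster, -0.16 to 0.078 for lantibiotic cluster 1, -0.47 to 0.22 for lantibiotic cluster 2, -0.35 to 0.012 for peroxide and superoxide, -0.15 to 0.024 for DNA repair, -0.037 to 0.11 for cell division and wall, -0.87 to 0.38 for the osdK/osdR region, -0.074 to 0.067 for the left arm and -0.084 to 0.11 for the right arm; the cause was not tested. With DESeq2 size factors DNA repair was at 0.0029, and with library size only cell division and wall was at -0.014 and the left arm at -0.0026. With the replicate block 0 list medians changed sign. Of 1422 values of 89 named genes under alternatives, 1308 kept direction and side of the threshold, 113 lost the call, 1 gained it and 0 reversed. Most of these genes were named for a small p or a large change in the same libraries, and 82 were called. Few reversals could therefore arise, and these counts say little about other genes. Of the calls lost, 44 were lost in the test against a log2 fold change of 1 and 30 with a required log2 fold change of 1.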

Other observations

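Of the 1328 genes called with ARC2, 312 lay in runs along the chromosome. Runs of at least 5 consecutive locus tag numbers called in 1 direction numbered 41, 23 higher and 18 lower. The longest, of 25 genes, held the actinorhodin cluster. In 1000 shuffles of the calls over the genes the longest run was 6 and no shuffle gave more than 2 runs. The shuffles treat neighbouring genes as independent, so they show only that calls were not placed independently of position. Why neighbours moved together was not tested. Of the 41 runs, 32 held no gene of a list other than the chromosome arms, 18 higher and 14 lower; the run from SCO6201 to SCO6206 had 6 genes and a median log2 fold change of 3.46, and a run of 9 genes that fell had a median of -1.95. The runs were examined after the data were seen.

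All tests in the following paragraphs but the nickel test were chosen only after the results were seen. All 14 nuo genes fell while the ATP synthase genes did not pass the test. One factor per library moves every gene alike and cannot part the nuo median from that of the ATP synthase genes, which differed by -2.80 log2 units. The nuo median was -2.58 with TMM, -2.55 with DESeq2 size factors and -2.61 with library size only, while genes called lower numbered 709, 623 and 1005, so scaling is argued against; the difference also drew attention to the pattern and serves only to exclude. A general fall of energy and translation genes, as in slower growth, was set to need medians at or below -1 in 3 lists. The medians were 0.22 for ATP synthase, 0.41 for the tricarboxylic acid cycle and 0.21 for ribosomal proteins. As lists, these did not share the nuo fall relative to other genes. The limit was set after the values were known, and scaling removes a fall common to all genes, so slower growth cannot be decided here. An effect of ARC2 on complex I may remain, as an untested hypothesis, and growth effects, and reads shared or antisense, stay open.

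All 22 actinorhodin genes, all 22 undecylprodigiosin genes and 31 of 40 calcium-dependent antibiotic genes rose, while SCO3219 of the last fell; the 3 list calls were lost with an estimated correlation (adjusted p = 0.452, 0.557 and 0.946). If the rise rested on 1 library alone, some pairing of an ARC2 with a DMSO library would give a median of 0 or below. The lowest of the 4 pairings in these 3 clusters was 0.68. This pattern was picked for its rise, so the outcome was largely set beforehand. The coelimycin cluster, also called higher by camera with its preset correlation, was left out of this pattern. Its pairings ran from -0.23 to 1.40, so they did not all lie above 0. A library that stands apart could still change the size of the rise: the undecylprodigiosin pairings ran from 1.70 to 3.18. A few abundant genes taking more of the counts with ARC2 would lower the other genes, not raise them. The median of all genes with library size as the only scaling was -0.030, which bears on the scaling and gives no test of the rise. In the 3 clusters of this pattern, the pairings show only that the direction of the rise did not rest on 1 library. The coelimycin pairings do not show this. A response to ARC2 is a possible explanation that the design names, and antisense reads and shared growth differences between the cultures stay open.

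The gene sodF fell together with genes of the nik locus for nickel uptake (nikA, SCO6451, at -2.10; nikB, SCO6452, -1.89; nikC, SCO6453, -1.96; nikD, SCO6454, -0.99), while nikE (SCO6455) was at -0.10 and did not pass the test (edgeR adjusted p = 0.786). The nik locus was chosen after its values were seen. A candidate explanation is more of the nickel-bound repressor Nur, which would lower all 5 nik genes and have sodN (SCO5254) called higher, a prediction made before the value of sodN was seen. The log2 fold change of sodN was 0.49 (95% interval 0.13 to 0.84), with an edgeR adjusted p of 0.0618, although the authors' deposited table gives 0.0115. The sodN interval lies above 0 but nikE did not fall, so the explanation cannot be told apart from others here, and nickel was not measured.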
